A study of Homo sapiens with 6 samples.

How the data were processed

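Total RNA of 6 cultures of human endometrial stromal cells, 3 untransfected and 3 lipofected with a miR-371a-3p mimic, was measured on Clariom S human arrays. Per the labels' protocols, only RNA with an integrity number above 8.0 was used, and it was amplified, biotin-labelled and hybridized with the WT PLUS chemistry. The deposited values are log2 expression values made with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarizes the probes of a probe set. Its version and library files are not given in the sources used here. The base of the logarithm was inferred from the range of the values, 1.77 to 14.20, and the values are neither ratios to a control nor centred per gene. RMA normalizes probes before it summarizes them, so the probe sets of these arrays could still differ in spread, with interquartile ranges from 3.08 to 3.40. A change that moved most transcripts one way would be largely hidden.

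The table held 27189 rows. The 21448 transcript probe sets were tested, without a filter on dim ones, and 5741 control rows and rows with plain numbers as IDs were left out. Platform annotation gave 1 gene symbol for 17709 tested probe sets, several for 0, and 3739 were unnamed here. All 17709 gene IDs matched the gene table used, and 0 symbols needed an update. A gene with several probe sets, true of 20 symbols, was represented by the brightest. HOXA10, a gene of the panel described below, had no named probe set and was not analysed here, and another panel gene is not reported here. Of 619 list entries, 566 were measured and 53 had no named probe set. No coordinates are given, since no genome build is named with the values.

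Groups were compared on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided, Benjamini-Hochberg adjustment over 21448 probe sets, threshold 0.05). Every adjusted p of a gene is from this fit. Before the data were examined, 23 gene lists were fixed: pathways and markers that fit stromal cells, transfection and implantation, and markers of other cell types. The lists were written from general knowledge. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 23 lists, and again with a correlation estimated per list. 11 lists were called, 7 higher and 4 lower, and 0 with the estimated correlation. The rotation test fry, which asks whether a list's own genes move one way on balance, called 15. A list's median change was also set against 10000 random lists matched on mean expression in 20 bins.

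The genes named were chosen by a rule fixed before the data were examined: per direction the 12 called genes with the largest change and no overlap between the groups, the 4 members of each list with the smallest p, and a fixed panel of 16 genes. The rule named 118 genes, of which 79 were called. Other called members of lists, among them PSAT1, ASNS, TIGAR and RRM2, were named after their values were seen. A level is called in the range of the negative rows when it was at or below the 95th percentile of the array's negative control rows on all arrays of a group. Of the called probe sets, 4 higher and 42 lower ones were in that range in both groups.

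The alternatives were another moderation of the variance, a test without moderation, the brighter part of the probe sets, quantile normalization again, median centring, cyclic loess, the replicate number as a block, array weights, fold thresholds, named probe sets alone and each array left out in turn. Scaling the arrays to one spread, using all rows of the table and the matched random lists were added after the data were seen. A planned test of miR-371a-3p seed sites in 3' untranslated regions was not run, since it needs transcript sequences, which were not used here.

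The scripts were tested on simulated data with the same number of arrays and 21448 probe sets. Of 50 probe sets changed at each size, limma recovered 20% at a log2 change of 0.5 and 100% at 1, 1.5 and 2, with 8 calls among the unchanged ones. In simulated data camera called 3.0% of 200 lists without a shift. The simulated genes varied independently, while the measured genes of G2/M and mitosis had an estimated correlation of 0.28. The simulation therefore does not show how often camera errs on correlated lists. Figures were drawn with matplotlib 3.10.9.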

Results

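Transcript levels were measured on Clariom S human arrays, which hold probe sets for well annotated genes, in cultured human endometrial stromal cells. These are the fibroblast-like cells of the uterine lining that can turn into decidual cells, here a line from a cell bank kept in serum with puromycin. In the mimic group, 3 samples had been lipofected with 30 nM of a synthetic double-stranded RNA that stands in for mature miR-371a-3p and were collected after 72 h. The 3 control samples had grown in medium with neither mimic nor transfection reagent, so every difference between the groups covers the mimic and the transfection together. It also covers any technical difference between the arrays of the groups, of which the spike rows below may be a sign. The series set out to find transcripts that miR-371a may regulate, with implantation in view. The number of arrays, 3 per group, limits the precision. The labels name repeated transfections in triplicate plates without saying which plate each sample came from, so the p-values measure the spread between these samples, which may be technical.

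Median log2 values of the arrays lay between 6.34 and 6.41. Pearson correlations over all tested probe sets were 0.988 to 0.993 between arrays of a group and 0.978 to 0.987 between arrays of different groups. The first principal component held 48.6% of the variance and separated the groups. The control arrays had a narrower signal range, with interquartile ranges of 3.14, 3.26 and 3.08 against 3.26, 3.37 and 3.40 in the mimic arrays. The median log2 change ran from -0.13 in decile 3 of mean expression to 0.135 in decile 9.

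After the mimic, 818 of 21448 probe sets were higher and 526 lower in limma at an adjusted p under 0.05. MEST, an imprinted gene of the mesoderm, rose most, from 6.45 ± 0.15 to 8.42 ± 0.014 (SD, n = 3), which is 3.93-fold (limma, adjusted p = 6.63e-04). PLBD1, a phospholipase B-like protein, fell most, from 7.99 ± 0.067 to 6.16 ± 0.21, which is 3.56-fold (limma, adjusted p = 0.00174). Changes of at least 2-fold were found for 129 of the higher and 53 of the lower probe sets, and the median size of a called change was 0.69 on the log2 scale. The groups did not overlap at 31.8% of all probe sets, against 10% by chance.

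Next to MEST, the largest rises with their SE on the log2 scale were those of DES (1.79 ± 0.16), the intermediate filament of muscle, and PAPPA (1.78 ± 0.16), a secreted protease that cuts insulin-like growth factor binding proteins. CDC25A, a phosphatase that activates cyclin-dependent kinases, rose by 1.75 ± 0.19, and SVIL, an actin-binding protein, by 1.73 ± 0.20. SVIL was above the range of the negative rows (their 95th percentile) on 1 of 3 control arrays, and CDC25A, CLCN5 and ZGRF1 on 2 of 3, so the size of these rises is uncertain. The others among the 12 largest were LRRC17 (1.68), IL1RAP, a co-receptor for interleukin-1 (1.65), ENTPD7 (1.64), CLDN12, a claudin (1.59), CLCN5, a chloride and proton exchanger (1.57), PLAU, the urokinase-type plasminogen activator (1.55), and ZGRF1 (1.50). Their limma adjusted p lay between 6.63e-04 and 0.00494.

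Among the falls, PLBD1 was followed by RGCC, a regulator of the cell cycle (-1.64 ± 0.17, SE), KCND2, a potassium channel (-1.61 ± 0.17), and PLN, an inhibitor of the calcium pump of muscle (-1.51 ± 0.19), which was above the range of the negative rows on 1 of 3 mimic arrays. IGFBP3, a binding protein for insulin-like growth factors, fell by 1.47 ± 0.13. Changes between -1.36 and -1.28 were found for CDH6, a cadherin, ARSB, a lysosomal sulfatase, C12orf75, INPP4B, a phosphoinositide phosphatase, SLC14A1, a urea transporter, ZNF804A and DAZAP2. The limma adjusted p of the 12 lay between 0.00174 and 0.00575. All 24 of these genes kept their call when each array was left out in turn.

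**Figure D1:**
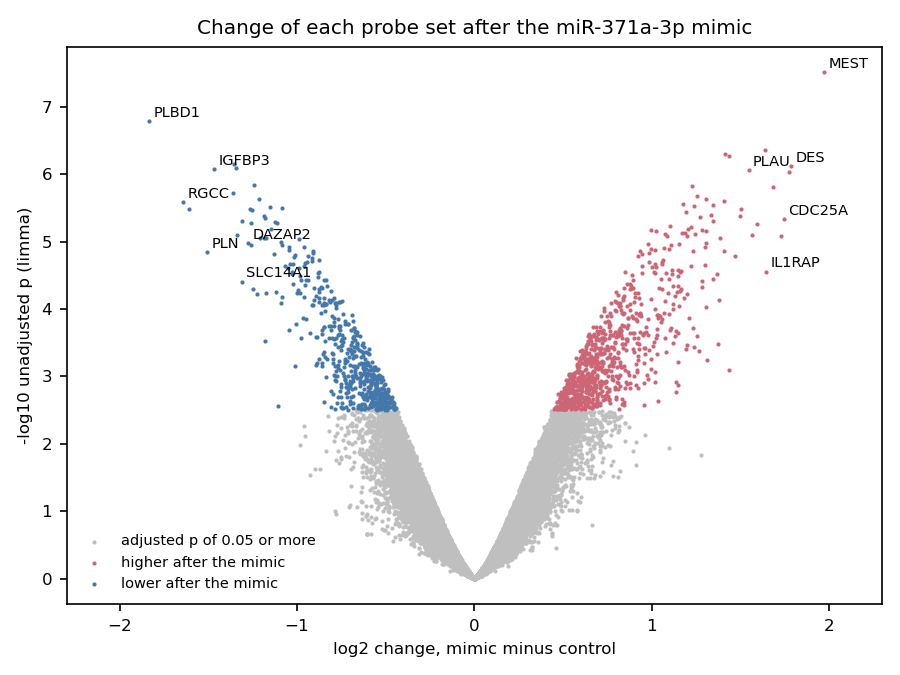
Each point is 1 of the 21448 tested probe sets, of which 22 are not drawn. The horizontal axis gives the log2 change (mimic minus control) and the vertical axis -log10 of limma's unadjusted p. Probe sets called higher or lower, 818 and 526 among all tested, are coloured where drawn, and the changes end at 1.97 for MEST and -1.83 for PLBD1.

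The counts depended on 5 of the 6 arrays. Without control 1, control 3, mimic 1, mimic 2 or mimic 3 in turn, limma called 358, 350, 372, 225 and 155 probe sets higher and 249, 243, 205, 150 and 129 lower. Without control 2 it called 909 and 512. A test without moderation of the variance called 26 and 36. Of the 79 called genes that the fixed rule named, 47 kept their call when each array was left out in turn, and the other 32 lost it without at least 1 array.

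Genes of cell division rose as a group. Of 35 measured genes of G2/M and mitosis, 12 rose, 0 fell and 23 did not pass, and 25 rose when p was adjusted over the list alone. NUF2 and NDC80, kinetochore proteins, rose by 1.03 and 0.69 on the log2 scale, TOP2A, a topoisomerase, by 0.74, and AURKB, a mitotic kinase, by 0.69. MKI67, a marker of dividing cells, was at 10.19 ± 0.25 in controls and 10.16 ± 0.52 after the mimic (SD, n = 3; limma, adjusted p = 0.949). Of 34 genes of G1/S and DNA replication, 8 rose and 1 fell (16 and 1 adjusted over the list alone). GINS1 (0.89), MCM10 (0.79), RFC3 (0.77) and DTL (0.76) rose, and RRM2, a subunit of ribonucleotide reductase, fell by 0.76. Both lists passed camera, a test of a list against all other genes, with an adjusted p of 5.19e-15 and 8.92e-08. With an estimated correlation the adjusted p was 0.188 for each.

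Genes known as targets of p53 were higher as a list, though not all of them. Of 22 measured, 8 rose and 1 fell (15 and 2 adjusted over the list alone). TIGAR, an enzyme that lowers glycolytic flux, rose by 1.31, SESN1, a stress sensor, by 1.22, TNFRSF10B, a death receptor, by 1.18, and MDM2, the ubiquitin ligase of p53, by 1.12. CDKN1A, the cyclin-dependent kinase inhibitor p21, fell from 10.81 ± 0.077 to 10.25 ± 0.034 (SD, n = 3; limma, adjusted p = 0.0243). That call was lost without each array other than control 2. TP53I3, a quinone oxidoreductase, was the other gene lower over the list alone, with a change of -0.53 ± 0.15 (SE; limma, adjusted p = 0.065 over all probe sets). The list passed camera with an adjusted p of 8.92e-08, and had an adjusted p of 0.188 with an estimated correlation.

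Of 27 genes of the unfolded protein response and of ATF4, a factor that answers amino acid shortage, 11 rose and 0 fell (16 and 0 adjusted over the list alone). PSAT1 (1.37) and PHGDH (1.03) make serine, ASNS (1.27) makes asparagine, and SLC7A11 (1.06) and SLC3A2 (0.59) form the cystine transporter. PSAT1 was at 9.80, 9.75 and 8.79 on controls 1, 2 and 3, and ASNS at 9.36, 9.43 and 8.42. The size of the PSAT1 and ASNS rises thus leans on control 3 and is uncertain. CHAC1, which degrades glutathione, rose by 1.10, and ATF4 itself by 0.52. The camera adjusted p was 2.97e-09, and it was 0.188 with an estimated correlation. The list pools both kinds of genes, and 23 had a positive change and 4 a negative one. The latter include DNAJB9, DNAJC3 and SDF2L1 of the unfolded protein response. DNAJC3 hardly changed, with 8.47 to 8.70 on the control arrays and 8.45 to 8.66 on the mimic arrays. Other genes of this response, among them HSPA5, EDEM1, PDIA4, PDIA6 and XBP1, were higher on every mimic array than on any control array. The list shares SESN2 with the p53 targets.

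**Figure D2:**
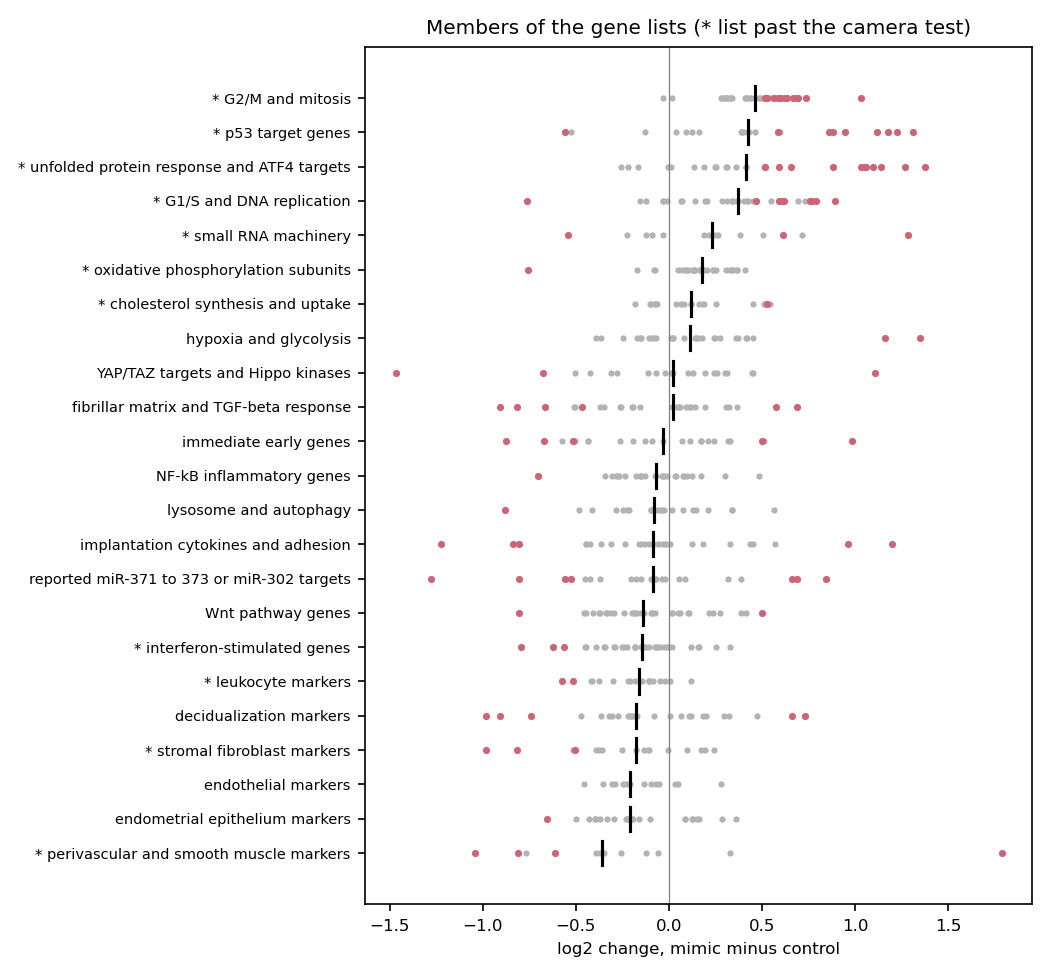
Log2 changes (mimic minus control, horizontal axis) of the measured members of the 23 gene lists (rows), in red where limma's adjusted p was under 0.05, with a bar at the median of each list. The medians run from 0.46 for G2/M and mitosis to -0.36 for perivascular and smooth muscle markers, and a star marks the 11 lists past camera.

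The called markers of decidualization went both ways. The treatment labels name only control or mimic, with no stimulus for decidualization. Of 26 measured, 2 rose and 3 fell (3 and 3 adjusted over the list alone). PRLR, the prolactin receptor, above the range of the negative rows on 2 of 3 control arrays, rose by 0.73 and TXNIP, an inhibitor of thioredoxin, by 0.66. DCN, the matrix proteoglycan decorin, fell from 10.96 ± 0.16 to 9.98 ± 0.14 (SD, n = 3), PGR, the progesterone receptor, from 7.74 ± 0.086 to 6.84 ± 0.17, and IRS2, an adaptor of insulin signalling, by 0.74 on the log2 scale. The classical markers did not pass: PRL changed by 0.32 ± 0.19 (SE) within the range of the negative rows in both groups, IGFBP1 by -0.17 ± 0.16, FOXO1 by -0.08 ± 0.12 and HAND2 by -0.36 ± 0.12, with limma adjusted p of 0.311, 0.527, 0.692 and 0.106. The list's camera adjusted p was 0.374, and the list was called lower within the brighter part of the probe sets (0.0496). The list's median change of -0.18 lay below that of random lists matched on mean expression, whose central 95% ran from -0.15 to 0.14, and fry gave an adjusted p of 0.025 in the lower direction.

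Of 27 cytokine and adhesion genes of implantation, 2 rose and 3 fell (5 and 6 adjusted over the list alone). The camera adjusted p was 0.404, and 0.024 within the brighter part of the probe sets, where the list was called lower. HBEGF, a growth factor of the epidermal growth factor family, rose by 0.96. LIFR, the receptor of leukaemia inhibitory factor, was called higher, but was in the range of the negative rows on all 3 control arrays and exceeded it on 1 of 3 mimic arrays, so no fold is given. It lost the call without control 1, control 3, mimic 2 or mimic 3. MMP3, a matrix metalloproteinase, fell by 1.22, CDH2, N-cadherin, by 0.84 and DKK1, a secreted Wnt inhibitor, by 0.81. LIF itself changed by -0.13 ± 0.15 (SE; limma, adjusted p = 0.62).

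Called genes among reported targets of the miR-371 to miR-373 cluster or of the related miR-302 family also went both ways. The list pools targets of several microRNAs and is not one of miR-371a-3p alone. Seed sites were not tested, so these changes do not show whether miR-371a-3p acts on the genes directly. Of 22 measured, 3 rose and 4 fell (4 and 7 adjusted over the list alone). DAZAP2 fell by 1.28, DKK1 by 0.81, CDKN1A by 0.56 and ARID4B by 0.53. WEE1, a kinase that holds back mitosis, rose by 0.85, TGFBR2, a receptor of transforming growth factor beta, by 0.69 and TXNIP by 0.66. LATS2, a Hippo kinase, changed by -0.07 ± 0.12 and CD44, the hyaluronan receptor, by -0.15 ± 0.11 (SE; limma, adjusted p = 0.759 and 0.437). The list had a camera adjusted p of 0.308, and was called lower after cyclic loess (0.0403) and after array scaling (0.00706). Its median change of -0.087 lay below the central 95% of matched random lists, -0.067 to 0.21, and fry gave an adjusted p of 0.0111 in the lower direction.

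**Figure D3:**
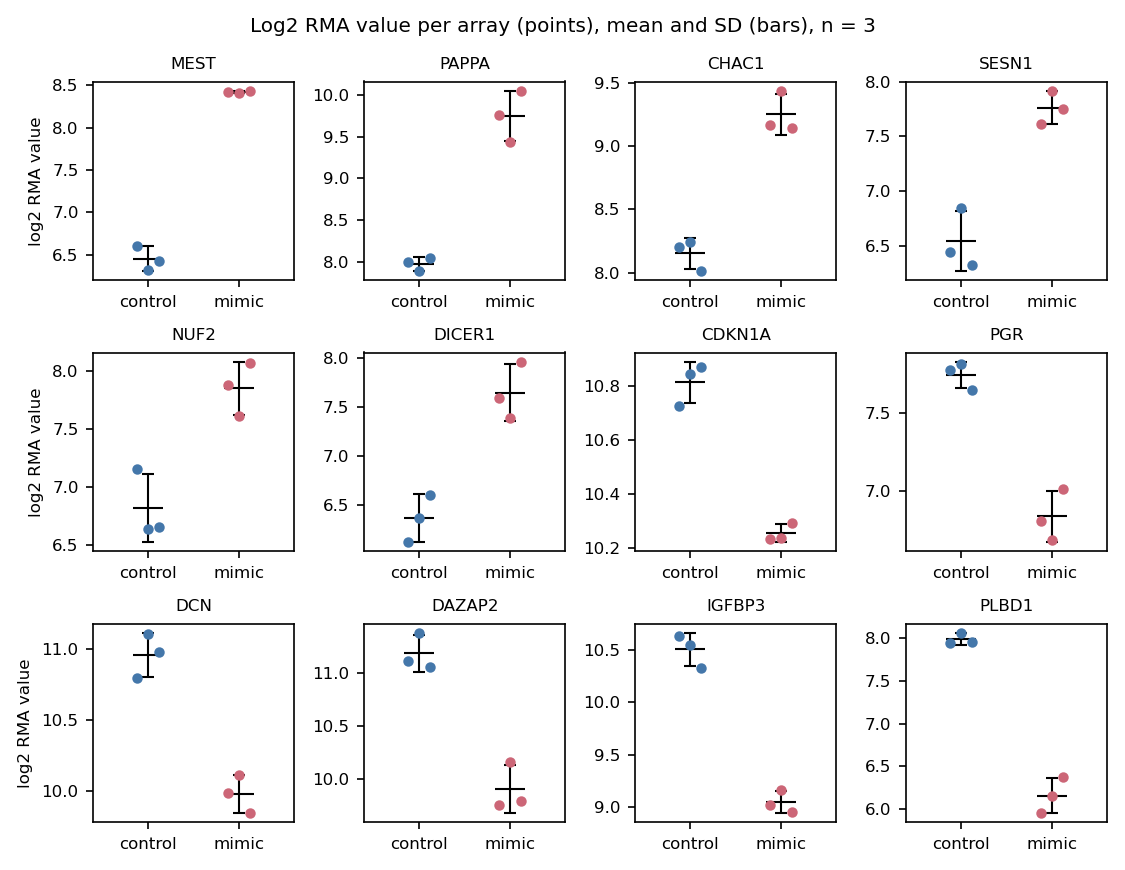
Log2 RMA values of 12 genes in the 3 control arrays (blue points) and the 3 mimic arrays (red points), with the mean and SD of each group in black and a separate vertical axis for each gene. The groups do not overlap for any of the 12, from MEST at 6.45 and 8.42 to PLBD1 at 7.99 and 6.16.

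In the machinery of small RNAs, 2 of 14 genes rose and 1 fell (4 and 1 adjusted over the list alone). DICER1, the nuclease that matures microRNAs, rose from 6.36 ± 0.24 to 7.65 ± 0.29 (SD, n = 3; limma, adjusted p = 0.00575), and XPO5, which exports their precursors, rose by 0.61. AGO1, an Argonaute protein, fell by 0.54, and AGO2 changed by -0.09 ± 0.17 (SE; limma, adjusted p = 0.751). The camera adjusted p was 0.0329, with 0.404 under an estimated correlation. Oxidative phosphorylation subunits were called higher as a list (camera, adjusted p = 0.00742; 0.4 with an estimated correlation), although 0 of 33 rose and SDHA, a subunit of complex II, fell by 0.76. Cholesterol genes were called higher (camera, adjusted p = 0.0276; 0.404 with an estimated correlation) with 1 of 20 rising, IDI1, by 0.53. These 3 lists were not called after cyclic loess, with adjusted p of 0.197, 0.239 and 0.197.

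Stromal and smooth muscle genes were lower. Of 17 stromal fibroblast markers, 0 rose and 3 fell (0 and 6 adjusted over the list alone): DCN by 0.98, LUM, the proteoglycan lumican, by 0.82 and FAP, a fibroblast protease, by 0.51. The camera adjusted p was 0.0242, with 0.188 under an estimated correlation. Of 12 perivascular and smooth muscle markers, DES rose and 3 fell (1 and 7 adjusted over the list alone), LMOD1 by 1.04, MYOCD, a coactivator of smooth muscle genes, by 0.81 and KCNJ8, a potassium channel, by 0.61. This list had a camera adjusted p of 0.0242, of 0.188 with an estimated correlation and of 0.0685 without mimic 2. Among 28 genes of the fibrillar matrix and the response to transforming growth factor beta, TGFBR2 and COL4A1 rose and THBS1 (-0.91), LUM, POSTN (-0.67) and TAGLN (-0.47) fell. Their median change was 0.021, their mean -0.09 and camera's direction lower (adjusted p = 0.374), and the list was called lower after cyclic loess (0.0403) and array scaling (1.00e-04).

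Interferon-stimulated genes were not higher 72 h after transfection with double-stranded RNA. Of 35 measured, 0 rose and 3 fell in either count: SAMD9 by 0.79, IFIT3 by 0.62 and DDX60, a helicase of antiviral defence, by 0.57. IFIT1 changed by -0.45 ± 0.14 (SE; limma, adjusted p = 0.0848). The camera adjusted p was 0.0242, with 0.188 under an estimated correlation and 0.103 after array scaling. Of 27 inflammatory genes driven by NF-kB, CCL2, a chemokine for monocytes, fell by 0.70 and the others did not pass (camera, adjusted p = 0.395).

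The remaining lists held single changes. SLC2A3, a glucose transporter, rose by 1.35 and PDK1, which slows pyruvate oxidation, by 1.16 among 28 genes of hypoxia and glycolysis (camera, adjusted p = 0.0543), a list called higher with a trended and robust prior (0.0286), without control 2 (0.0472) and without mimic 1 (0.044). The SLC2A3 value is uncertain, since SLC2A14 is a near-identical copy. Among 21 targets of YAP and TAZ or Hippo kinases, ANKRD1 rose by 1.11 and IGFBP3 and F3, tissue factor, fell (camera, adjusted p = 0.998; median 0.021, mean -0.014, direction lower). Of 23 immediate early genes, DUSP5 (0.98) and MYC (0.50) rose and EGR3 (-0.87), EGR1 (-0.67) and KLF2 (-0.52) fell (camera, adjusted p = 0.876). Of 33 genes of the Wnt pathway, MYC rose and DKK1 fell (camera, adjusted p = 0.161). LAMP1, a lysosomal membrane protein, fell by 0.88 and was the only called gene of 25 in the lysosome and autophagy list (camera, adjusted p = 0.413), which was called lower after cyclic loess (0.0403) and array scaling (0.00688). In the comparison with random lists matched on mean expression, 10 of the 23 medians lay outside the central 95%. Those were higher for mitosis, replication, p53 targets and the pooled list of unfolded protein response and ATF4 genes. They were lower for stromal, perivascular, epithelial, decidualization, lysosome and reported target genes.

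Markers of leukocytes, epithelium and endothelium had median changes of -0.16, -0.21 and -0.21. Of 18 leukocyte markers, CD68 (-0.57) and TYROBP (-0.52) fell and 0 rose, and the list was called lower (camera, adjusted p = 0.0242; 0.196 with an estimated correlation; 0.0911 after cyclic loess). MUC16, a mucin, fell by 0.66 among 24 epithelial markers (camera, adjusted p = 0.112, and 0.0218 without control 2), and 0 of 15 endothelial markers passed (camera, adjusted p = 0.161). Of these 57 markers, 33 lay above the 95th percentile of the negative rows in all 3 control arrays. EPCAM and CDH1, epithelial adhesion proteins, PTPRC, LYZ and HLA-DRA of leukocytes and PECAM1 of endothelium were below it in every control array.

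Rows outside the tested probe sets differed between the groups as well. The hybridization spike rows bioB, bioC, bioD and cre had a mean log2 value of 11.55 ± 0.14 in the control arrays and 10.97 ± 0.18 in the mimic arrays (SD, n = 3; two-sided exact permutation p = 0.10). The labelling spike rows dap, lys, phe and thr had 8.15 ± 0.30 and 8.55 ± 0.058 (two-sided exact permutation p = 0.10). With 3 arrays against 3, 0.10 is the smallest p this test can give. Spikes are not transcripts of the cells. A technical difference between the arrays of the groups therefore cannot be told apart from the mimic and the transfection.

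**Figure D4:**
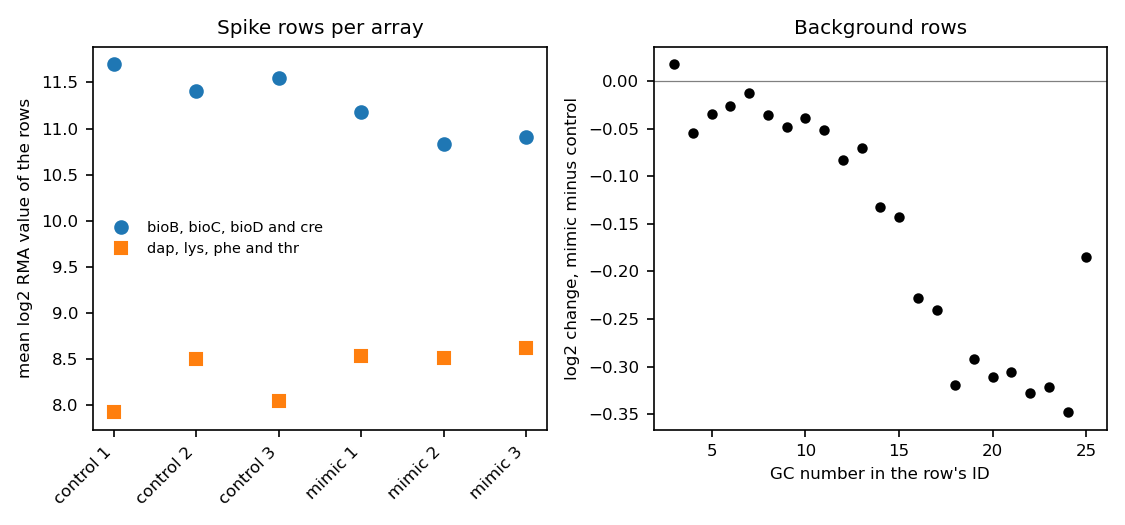
Left, the mean log2 RMA value of the spike rows on each of the 6 arrays, with bioB, bioC, bioD and cre as circles and dap, lys, phe and thr as squares. Right, the log2 change (mimic minus control) of the 23 background rows against the GC number in the row's ID, where the 8 rows with 18 or more have a median of -0.315 and the 10 rows with 12 or fewer a median of -0.037.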

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

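The tests of spike rows and of chance splits, the comparisons on the levels of the markers and the one on background rows were chosen after the values were seen. The matched random lists were applied after the lists' medians were known, with the outcome that would count written first.

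Among rows outside the main measurement, 10 rows with plain numbers as IDs and 3 positive control rows were higher after the mimic in limma at an adjusted p under 0.05, and 1 row with a plain number was lower. The mean log2 change of the spike rows bioB, bioC, bioD and cre was -0.58, and that of dap, lys, phe and thr was 0.40, with 0 single spike rows past the threshold. These values were flagged because the rows are not part of the tested probe sets and their values or counts stood apart between mimic and control arrays.

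The real grouping called 1344 probe sets, and 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, reached that number. The highest other split called 0. With 10 splits no share under 0.05 is possible.

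Markers of leukocytes, epithelium and endothelium leaned to lower values after the mimic, with a pooled median change of -0.20 over 57 genes. For the pooled markers the narrower signal range of the control arrays is not the whole cause by this test, since lists matched on expression had medians from -0.15 to 0.006 (central 95%). Taken alone, the epithelial list lay below its matched range (-0.208 against -0.196 to 0.039). The leukocyte list (-0.164 against -0.206 to 0.048) and the endothelial list (-0.2075 against -0.2131 to 0.1285) lay within theirs. For leukocyte and endothelial markers the narrower range therefore stays open. Fewer cells of other types in the mimic wells stays open. The outcome written first was met, at percentile 0.07 of the matched lists. That value restates the fall that prompted the test, so it is no separate support. The cultures were of a line from a cell bank, and no value here shows that they held other cell types. In the 33 markers above the range of the negative rows in all control arrays the median change was -0.22, and -0.14 in the others. PTPRC, LYZ, HLA-DRA, EPCAM, CDH1 and PECAM1 lay below that range in the control arrays, with a median level of 3.65 against 4.52 for its lowest upper bound (95th percentile), and levels that low decide nothing either way. Background signal that depends on the GC content of the probes stays open too: background rows with 18 or more GC bases had a median change of -0.315, and the GC content of the markers' probes was not analysed here.

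Mitosis and replication genes were higher, with a median change of 0.42 over 69 genes. The narrower signal range of the control arrays is argued against, since lists matched on expression had medians between -0.015 and 0.17 (central 95%). The random lists were not matched on the GC content of the probes, so an effect of it was not tested for these genes. An effect of the transfection itself and not of the mimic sequence cannot be told apart from one of the mimic, because 0 arrays hold cells given the reagent without the mimic. The lower CDKN1A level beside the higher list of p53 targets is a value of the same comparison and has the same limit.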

How the results depend on the processing

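Array scaling and the use of all rows were chosen after the data were seen. No called gene among those the rule named, and no called list, reversed in the alternatives run. Limma with a trended and robust prior called 1837 probe sets higher and 992 lower, the brighter part of the probe sets gave 1757 and 939 with fewer tests, and an unmoderated equal-variance test gave 26 and 36. The cause was not tested for the first and last. Leaving out each array in turn gave 155 to 909 higher, 129 to 512 lower and 8 to 13 lists, with the lowest probe set counts without mimic 3 and the highest count of rises without control 2. The replicate number as a replicate block gave 419 higher and 251 lower. Deviations of same-numbered arrays correlated at 0.04, 0.09 and -0.08, and not every array correlated best with its own number. That gives no sign of pairing, but 3 arrays per group cannot exclude a shared plate or round of transfection. Of 11 lists, 0 were called with an estimated correlation and 7 after quantile normalization again (the cause was not tested). Every other count stayed within 1.5 times, though array scaling lost 5 lists and gained 3, and cyclic loess lost 4 and gained 3. The share of higher calls, 60.9%, lay between 54.4% and 69.3% under other scalings. The lists of mitosis, replication, p53 targets and stromal markers were called in every alternative other than the estimated correlation. So was the pooled list of unfolded protein response and ATF4 genes. Of 79 called named genes, 47 kept the call without any array and 10 in the unmoderated test. Over the alternative fits, leaving aside the estimated correlation, fry and the matched lists, the named genes lost 226 calls and gained 56, and the lists lost 24 and gained 12. Simulated changes of 0.5 were recovered at 20%, so small changes can be missed. The seed site test and its alternatives were not run.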

Other observations

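The lists in this part were drawn up after the table of all genes had been examined, so their counts describe these arrays and test nothing, except where a test is named below. Of 9 measured enzymes and readers of DNA methylation, 4 rose. TET1 (1.41 ± 0.17, SE, log2 change) and TET2 (0.74), which oxidize methylcytosine, DNMT3B (1.19), a methyltransferase, and TDG (1.07), which excises the oxidized base, passed (limma, adjusted p from 0.00358 to 0.0256), and 5, among them DNMT1 and DNMT3A, did not. All 16 measured cytosolic aminoacyl-tRNA synthetases had a positive change with a median of 0.43, and AARS1 (0.62), IARS1 (0.64) and LARS1 (0.62) rose (limma, adjusted p from 0.0198 to 0.0419).

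Of 12 non-clustered protocadherins, adhesion proteins related to cadherins, 5 fell and 0 rose. PCDH10 fell by 1.21, PCDH9 by 1.17, PCDH19 by 1.11, PCDH18 by 1.09 and PCDH7 by 0.85 on the log2 scale (limma, adjusted p from 0.00251 to 0.0473). In the insulin-like growth factor axis, PAPPA rose and IGFBP3 (-1.47), IGFBP5 (-1.15), IRS2 (-0.74) and IGFBP6 (-0.45) fell, 4 of 15 measured, while IGF1, IGF2 and IGF1R changed by -0.22, -0.12 and 0.17 (limma, adjusted p of 0.293, 0.539 and 0.475).

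Several of the largest rises are known targets of let-7, a microRNA that differentiated cells hold in large amounts. Besides PAPPA, CDC25A, CLDN12 and DICER1 they include HMGA2 (1.50), CCNJ (1.31) and CDK6 (1.22), and 10 such genes were seen first. A hypothesis is that the mimic may displace endogenous microRNAs from Argonaute. It was tested on 37 measured let-7 targets written down without those 10, with the outcome that would count written before the test. The table of all genes had been examined by then, so none of the 37 can be called unseen, and 3 of them (AGO4, CCND2 and TGFBR1) are in other lists. The median change of the 37 was 0.24, against -0.12 to 0.11 in matched random lists (central 95%), and it stayed between 0.22 and 0.31 without each array. Of the 37, 29 had a positive change, and 9 rose, among them IGF2BP2 and DNA2, and 0 fell. The others did not pass, among them IGF2BP1 (0.041), TRIM71 (0.117) and E2F5 (0.128). The 34 genes outside the other lists, a check added afterwards, had a median of 0.24 against -0.135 to 0.11, which does not make the test independent.

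Against other readings of the let-7 result, the percentile of 99.99 among lists matched on expression argues against the narrower signal range of the control arrays. Targets of miR-124 and miR-122 had a median of 0.024 against -0.05 to 0.21 in matched lists, and -0.051 after cyclic loess. By the outcome written first, that argues against a property shared by microRNA targets in general. Both target lists were written after the table of all genes had been examined, so the choice of their members could have made this contrast. A shift of the cell cycle stays open, since 0 of the 37 genes are in the cell cycle lists and leaving none out tests nothing. An effect of the transfection itself and not of the mimic sequence stays open too, with 0 arrays of cells given the reagent without the mimic. The random lists were not matched on the GC content of the probes, so an effect of it on the let-7 targets was not tested. Targets of miR-21 and miR-29 pooled had a median of 0.136, at percentile 95.45 of matched lists, which leaves the displacement hypothesis undecided for them. The miR-29 list alone stood at 0.23 (percentile 99.15 of matched lists), between 0.15 and 0.30 without each array, or at 0.139 after cyclic loess (percentile 97.28). It is not independent of the lists above, since 17 of its 25 genes are in other lists, DNMT3B, TDG and TET2 among them. Its unadjusted camera p was 3.89e-05, and 0.14 with an estimated correlation. The miR-21 list stood at -0.06 (percentile 18.29), between -0.10 and 0.082 without each array, so that its sign turned, or at 0.033 after cyclic loess (percentile 63.01).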
